A study of Homo sapiens with 30 samples.

How the data were processed

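RNA sequencing was reported for CD14+ monocytes from the blood of healthy donors, 30 libraries in 10 groups of 3. In 1 set of 12 libraries, cells spent a night in M-CSF at 20 ng/ml, alone or together with IL-10 at 100 ng/ml, and were then left unstimulated or given LPS at 10 ng/ml for 3 h. A second set of 12 libraries followed the same scheme with TNF at 20 ng/ml for 6 h. The remaining 6 libraries came from cells edited with CRISPR at HPRT, the control locus, or at both IRF1 and IRF5, and given LPS for 3 h; per the series description, 48 h passed after editing. The 2 larger sets are called the LPS set and the TNF set below. Replicates are separate donors per the labels, the donors of the TNF set carry other numbers than those of the LPS and edited sets, and nothing else about the donors was used.

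Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt and aligned with STAR to hg38; versions, the counting tool, the annotation and the low-count rule are not given in the sources used here. The deposited values are raw counts per Ensembl gene from poly(A)-selected, directional libraries, from which the authors had already removed genes with few reads. The LPS set had 11059 genes, the TNF set 10811 and the edited cells 11745, of which 10930 were in both the LPS and edited tables, 10558 in both the LPS and TNF tables and 10491 in all 3. Gene symbols, types and GRCh38 (hg38) coordinates came from GENCODE release 29 by gene ID, which matched 11042, 10793 and 11706 genes; 10359, 10233 and 10738 of these are protein coding. No symbol occurred more than once within a table. The table of edited cells also held 3 resting libraries whose counts were identical to those of the LPS set for 100% of shared genes; they were left out of the editing fit and counted once.

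Total counts per library ran from 3212829 to 43182004 in the LPS set, from 7265200 to 44948785 in the TNF set and from 746227 to 1599504 in the edited cells. With 3 counts taken as a floor, a gene absent from a whole edited group is below 0.906 CPM in that group, against 0.0504 CPM in the LPS group. The 10 most abundant genes took 7.60 to 9.90% of the counts per group on average. No mitochondrially encoded transcript is in any table, so their share was not used here as a measure of RNA quality. Counts of pairs of replicates differed far beyond counting error, with chi-square per degree of freedom from 3.66 to 131, so all tests estimated the spread between donors. Reads were counted without molecular identifiers as far as the labels tell, so the floors cover counting error only.

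Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, robust dispersion, TMM factors, R 4.3.3) on all genes of a table, without further filtering, with 1 mean per group and no donor term. The 12 libraries of a set shared 1 fit, and the 6 edited libraries another. Unless a sentence says otherwise, p values are adjusted p values of this edgeR test by the Benjamini-Hochberg method over all genes of the table, and a gene is called changed below 0.05. Fold changes are log2 values with n = 3 per group. Their standard errors were derived from the test, as the absolute log2 fold change divided by the square root of F. They are approximate, above all for genes near 0 in a group. Levels are CPM (counts scaled to the library total after TMM), mean and SD over the 3 libraries. The main tests were 4 comparisons in each set: the stimulus against resting, IL-10 before the stimulus against the stimulus, IL-10 alone against resting, and the interaction, the difference between the IL-10 effects with and without the stimulus. The edited groups were compared with each other, and 1 fit over the 24 libraries of both sets (10558 genes) tested whether the IL-10 effect differed between LPS and TNF. Overlaps of gene sets were set against the number expected for independent sets of the same size. Because LPS or TNF libraries enter both sides of the stimulus and IL-10 overlaps, these were also simulated 20 times without any IL-10 effect. These choices were made before the data were examined.

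To describe groups of genes, 29 lists were fixed before the data were examined: interferon-stimulated genes; interferon-gamma-type and guanylate-binding protein genes; interferon genes; inflammatory cytokines; chemokines; NF-kB feedback and target genes; IL-10 and STAT3 target genes; scavenger, phagocytic and complement receptors; interferon regulatory factors; AP-1, EGR and MAF factors; MHC class II and costimulation; MHC class I processing; inflammasome; glycolysis and HIF-1 targets; cholesterol synthesis; metallothioneins; p53 targets; unfolded protein response; cell cycle; monocyte identity; markers of T and NK cells, B and plasma cells, platelets, neutrophils, dendritic cells and erythroid cells; mitochondrially encoded transcripts; ribosomal proteins; and reference genes. Some genes are in more than 1 list, for example CXCL10 and FCGR1A. Each list was described by its members called over all genes, by its members called when p was adjusted over the list alone, and by camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists). The camera test with a correlation estimated from the data is given beside it. Genes named are IRF1, IRF5 and HPRT1 after editing, up to 5 genes with the largest rise and up to 5 with the largest fall in each main comparison (3 in the others), up to 3 per list, all called, with mean log2 CPM of at least 3 and the same direction in all 3 donors, and a panel of 12 genes whatever their values. Sex-linked genes used for sample checks, genes whose presence varies by genotype, and features known only by a clone name were not named.

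The labels name the donor of each library. After subtracting group means, libraries with the same number correlated with r from 0.232 to 0.547 in all 18 pairs of the LPS set (other pairs from -0.321 to -0.0465), from 0.304 to 0.341 in the 3 pairs of edited cells (others from -0.234 to -0.0700), and from -0.180 to 0.749 in the TNF set, where 12 of 18 pairs were above 0.1 (others from -0.654 to 0.680). No label states that donors were paired in a test, so the fit without a donor term leads, by a choice made beforehand. The value with the donor number as a replicate block stands beside a result that it changes. The block is a term added to the same edgeR test. Where a count by edgeR stands beside a block value, the fit without this term is meant. Same-numbered libraries varied together in the LPS set and the edited cells, and the leading fit leaves this pairing out. It called fewer genes than the block in every comparison, such as 90 against 806 after editing. A gene not called by it can still differ within donors.

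Alternatives fixed beforehand were the replicate block, RLE size factors, library size without TMM factors, edgeR's filterByExpr, DESeq2 1.42.0 (Wald test), fits of the 2 groups alone, each library left out in turn, and a 2-fold threshold. Chosen after the data were seen were thinning of libraries to 746227 counts, the depth of the shallowest edited library, equal depth in the edited groups, a block with a pair of donor numbers exchanged in the TNF group, and the leaving out of single libraries for the overlaps and the joint fit. Tested on simulated data built from the real tables, with 100 genes shifted per size, the test recovered 45% of 2-fold and 77% of 4-fold changes for IL-10 before LPS (9 false calls), 51% and 86% for IL-10 before TNF (10 false calls), 37% and 74% after editing (8 false calls), 10% and 56% for the interaction with LPS, and 18% and 68% for that with TNF. It called 0 genes in unchanged comparisons, and 0 of 50 random lists passed camera at 0.05. Simulated genes were drawn independently of each other and without donor effects, so this does not test the preset correlation of camera.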

Results

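Monocytes from 3 donors per group were compared after LPS or TNF, with and without a night in IL-10 beforehand, and after CRISPR editing of IRF1 and IRF5 before LPS. Counts for CCL3, CCL4, FCGR1A, the MT1 genes and HLA genes can include reads from closely similar genes, since how such reads were assigned is not given in the sources used here. Statements on which genes rose or fell most hold among genes with a mean log2 CPM of at least 3 and the same direction in all 3 donors, called abundant genes in the text.

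LPS, the ligand of the receptor TLR4, changed 5135 of 11059 genes at 3 h, 2634 higher and 2501 lower, and 3169 of them at least 2-fold. The largest rise of an abundant gene was in ACOD1, the enzyme that makes itaconate (ENSG00000102794, chromosome 13, 76948497 to 76958642), from 0.184 ± 0.247 to 2568 ± 677 CPM (log2 fold change 14.37 ± 0.64, adjusted p = 5.6e-09, n = 3 per group). TNIP3, an inhibitor of NF-kB signalling, rose by 11.20 ± 0.43, CD274, which encodes the checkpoint ligand PD-L1, by 10.47 ± 0.48, the cytokine IL1B by 9.24 ± 0.46 (605-fold) and the chemokine CCL4 by 9.06 ± 0.52. LPAR6 (-5.75 ± 0.33), RGS14 (-5.69 ± 0.33), GCNT1 (-5.67 ± 0.35), ENC1 (-5.13 ± 0.32) and GPRIN3 (-5.06 ± 0.28) fell most among abundant genes. Transcripts of IRF1, a transcription factor of interferon responses, rose 19.5-fold (4.28 ± 0.24), whereas IRF5 was -0.23 ± 0.23 and not called (adjusted p = 0.43). IL6 rose by 10.55 ± 1.59, TNF by 4.14 ± 0.31 and IL10 by 2.79 ± 0.32, and the haemoglobin scavenger receptor CD163 fell slightly (-0.51 ± 0.17).

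Among the fixed lists, 30 of 31 NF-kB feedback and target genes rose with LPS, such as TRAF1 (8.04 ± 0.43), with a median of 4.23 (camera adjusted p = 2.1e-20, and 0.031 with an estimated correlation). Of 44 interferon-stimulated genes, 40 rose and none fell, including CXCL10 (7.08 ± 0.52), ISG20 (6.65 ± 0.39) and IFIT2 (6.56 ± 0.55); the camera p was 9.7e-23, and 0.0495 with an estimated correlation. Interferon-gamma-type genes rose in 26 of 32 cases and fell in 1, with SOCS1 at 8.04 ± 0.47 and GBP4 at 7.82 ± 0.66. Chemokines rose in 17 of 22 cases, among them CCL5 (8.10 ± 0.74), and inflammatory cytokines in 14 of 17. The STAT3 target list had 19 genes higher and 5 lower of 28, led by IL2RA (8.59 ± 0.87) and SOCS3 (7.47 ± 0.31), a feedback inhibitor of cytokine receptors. AP-1, EGR and MAF factors had 14 higher and 3 lower of 22, with ATF3 at 4.58 ± 0.36 and FOS at -4.50 ± 0.59. MHC class I processing genes rose in 10 of 17 cases (TAP1, 2.80 ± 0.20), and unfolded protein response genes in 8 of 17 (XBP1, 2.08 ± 0.16). With an estimated correlation the adjusted p was 0.0495 for interferon-gamma-type genes and for cytokines and 0.031 for AP-1, EGR and MAF factors. It was 0.059 for chemokines, 0.057 for STAT3 targets, 0.13 for MHC class I processing and 0.059 for the unfolded protein response, so these 4 lists lost their call.

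Scavenger and phagocytic receptors had 11 lower and 1 higher of 26, with the receptor MERTK at -3.93 ± 0.29 (camera adjusted p = 0.084, 0.024 with a replicate block, and 0.13 with an estimated correlation). Monocyte identity genes had 7 lower and 4 higher of 20, such as the receptors CX3CR1 (-3.93 ± 0.79) and CCR2 (-3.59 ± 0.74). Inflammasome genes had 7 higher and 4 lower of 15 (CASP5, 4.10 ± 0.42), and glycolysis and HIF-1 targets 7 and 3 of 24 (PFKFB3, 3.92 ± 0.20). For cholesterol synthesis genes it was 5 higher and 6 lower of 23 (INSIG1, 3.04 ± 0.31), and for p53 targets 6 and 7 of 21 (PLK3, 3.21 ± 0.25). MHC class II and costimulation genes had 3 higher and 1 lower of 15 (CD83, 5.45 ± 0.32), metallothioneins 1 and 2 of 7 (MT1H, -1.05 ± 0.27), interferon regulatory factors 4 and 1 of 8 (IRF7, 2.75 ± 0.15), and cell cycle genes 1 and 6 of 9 (PCNA, -1.68 ± 0.29). Reference genes had 4 higher and 3 lower of 14, including the transferrin receptor TFRC (2.18 ± 0.28). Ribosomal protein genes rose in 3 of 32 cases (12 with the replicate block; list adjusted p = 0.054, 0.0038 with the block, and 0.68 with an estimated correlation), and RPL30 was 0.38 ± 0.14 with TMM factors but -0.07 with library size alone. Markers of other cells were mostly absent. No T and NK cell, erythroid, mitochondrially encoded or interferon gene of the lists was among the deposited genes of the LPS set. Why mitochondrially encoded transcripts are absent was not tested. The 2 measured B and plasma cell markers did not pass the test. Platelet (1 higher of 4), neutrophil (3 lower of 6) and dendritic cell markers (1 higher and 3 lower of 8) were few. Scaled by library size alone, 25.2% of called genes were higher in place of 51.3%, with the median log2 change shifted by -0.45.

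IL-10 by itself changed 1007 genes in otherwise resting cells of the LPS set, 590 higher and 417 lower. The hyaluronan-binding protein gene CEMIP rose most among abundant genes (9.06 ± 0.85), with TNIP3 (7.73 ± 0.39) and ENPP2, which encodes autotaxin (7.25 ± 0.63). SOCS3 rose 50.3-fold (5.65 ± 0.29), CD163 by 1.71 ± 0.18, and the proteoglycan gene VCAN by 3.31 ± 0.24. Of 28 STAT3 targets, 16 rose and 2 fell (camera adjusted p = 2.9e-15, and 0.015 with an estimated correlation), and 20 were higher when adjusted over the list alone. Scavenger and phagocytic receptors had 9 higher and 3 lower of 26, led by the complement receptor CR1 (6.43 ± 0.44), LYVE1 (4.91 ± 0.87) and the Fc receptor FCGR1A (3.75 ± 0.41), with adjusted p = 0.00044, and 0.032 with an estimated correlation. Interferon-stimulated genes fell in 29 of 44 cases and rose in 1, for example IFI44L (-4.18 ± 0.53), CMPK2 (-4.13 ± 0.55) and IFI6 (-3.92 ± 0.18); the median was -1.47, with adjusted p = 2.9e-15, and 0.101 with an estimated correlation. Metallothioneins, which bind zinc and copper, fell in 6 of 7 cases (MT1H, -2.49 ± 0.29; adjusted p = 1.3e-07, and 0.101 with an estimated correlation). IRF5 fell by 0.86 ± 0.23 (adjusted p = 0.030), while IRF1 stood at -0.03 ± 0.22 (adjusted p = 0.96). With the donor number as a block, 1755 genes were called (972 higher, 783 lower). By library size alone, 45.5% of called genes were higher in place of 58.6%, at a median shift of -0.11.

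To test what IL-10 changes in cells that then meet LPS, IL-10 plus LPS was compared with LPS. CXCL10, a chemokine induced by interferons (ENSG00000169245, chromosome 4, 76021117 to 76023497), fell 103-fold, from 490 ± 185 to 4.99 ± 1.28 CPM (log2 fold change -6.69 ± 0.52, adjusted p = 9.4e-06, n = 3 per group). The antiviral genes RSAD2 (-5.38 ± 0.44), IFIT1 (-4.86 ± 0.40) and IFI44L (-4.83 ± 0.50) and the death ligand TNFSF10 (-4.18 ± 0.67) followed. CR1 (ENSG00000203710, chromosome 1, 207496147 to 207641765) rose 169-fold (7.40 ± 0.48), from 2.39 ± 1.06 to 394 ± 30.7 CPM, ahead of CEMIP (5.71 ± 0.72), ENPP2 (5.34 ± 0.57), the transglutaminase subunit F13A1 (4.65 ± 0.31) and IL12RB2 (4.63 ± 0.76). IRF1 (ENSG00000125347, chromosome 5, 132481609 to 132490798) fell from 470 ± 107 to 136 ± 21.6 CPM (-1.79 ± 0.22, adjusted p = 0.00014), and IRF5 (ENSG00000128604, chromosome 7, 128937612 to 128950035) from 173 ± 40.3 to 53.5 ± 17.9 CPM (-1.68 ± 0.23, adjusted p = 0.00036). Altogether 1195 genes changed, 595 higher and 600 lower, and 709 of them at least 2-fold.

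Not every LPS-induced cytokine was lower with IL-10. TNF fell by 0.91 ± 0.27 (adjusted p = 0.049), IL6 was -1.79 ± 0.96 and not called (adjusted p = 0.31, and 0.012 with a replicate block), and IL1B (0.40 ± 0.32), SOCS3 (0.46 ± 0.24) and IL10 (0.11 ± 0.30) were not called. NF-kB feedback and target genes had 1 higher and 1 lower of 31 (TNIP3, 0.94 ± 0.27, and CD83, -1.02 ± 0.27), with camera adjusted p = 0.090; with the block 1 was higher and 4 lower, p = 0.0499, and p = 0.54 with an estimated correlation. Inflammatory cytokines fell in 4 of 17 cases (adjusted p = 0.0029, and 0.14 with an estimated correlation), and chemokines had 6 lower and 2 higher of 22, CCL5 among the former (-2.19 ± 0.55).

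Interferon-related lists fell with IL-10 under LPS. Of 44 interferon-stimulated genes 42 fell and none rose, 43 when adjusted over the list alone, with a median of -2.79 (camera adjusted p = 1.9e-64, and 0.0057 with an estimated correlation). Interferon-gamma-type genes fell in 17 of 32 cases and rose in 2 (APOL6, -2.76 ± 0.19; FCGR1A, 3.34 ± 0.42; adjusted p = 9.7e-15, and 0.041 with an estimated correlation). Interferon regulatory factors fell in 5 of 8 cases, IRF7 the most (-2.54 ± 0.15, from 290 to 49.9 CPM; list adjusted p = 0.00012, and 0.068 with an estimated correlation). MHC class I processing genes fell in 8 of 17 cases, 13 when adjusted over the list alone, such as PSMB9 (-1.81 ± 0.27) and TAP1 (-1.67 ± 0.19), with adjusted p = 3.7e-07, and 0.057 with an estimated correlation. Metallothioneins fell in 5 of 7 cases (MT1H, -2.10 ± 0.29; adjusted p = 1.0e-05, and 0.14 with an estimated correlation).

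Monocyte identity genes had 8 higher and 2 lower of 20 in the same comparison, with VCAN (3.86 ± 0.25) and S100A9 (2.73 ± 0.33) rising and FCN1 falling (-3.45 ± 0.54); the list median was 0.96 (adjusted p = 2.2e-06, and 0.034 with an estimated correlation). Scavenger and phagocytic receptors had 10 higher and 4 lower of 26 (CD163, 2.07 ± 0.18; LYVE1, 4.27 ± 0.86; adjusted p = 0.0071, and 0.057 with an estimated correlation), and STAT3 targets 9 higher and 2 lower of 28 (IL21R, 3.20 ± 0.34; adjusted p = 0.0015, and 0.079 with an estimated correlation). AP-1, EGR and MAF factors had 6 higher and 2 lower of 22, MAF itself at 2.87 ± 0.42 (list adjusted p = 0.062, 0.0499 with the block, and 0.13 with an estimated correlation). CD86, a costimulatory ligand, was among 2 of 15 MHC class II and costimulation genes that fell (-1.61 ± 0.19; with the block 5 fell). No cholesterol synthesis or ribosomal protein gene was called of 23 and 32, with 3 cholesterol synthesis genes higher and 1 lower under the block, and dendritic cell markers had 4 lower and 1 higher of 8 (adjusted p = 0.092, 0.010 with the block, and 0.19 with an estimated correlation). The ribosomal list had adjusted p = 0.071, 0.020 with the block, and 0.67 with an estimated correlation. With the donor number as a block, 2032 genes were called in all (1033 higher, 999 lower), and 750 after thinning to the depth of the shallowest edited library.

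**Figure D1:**
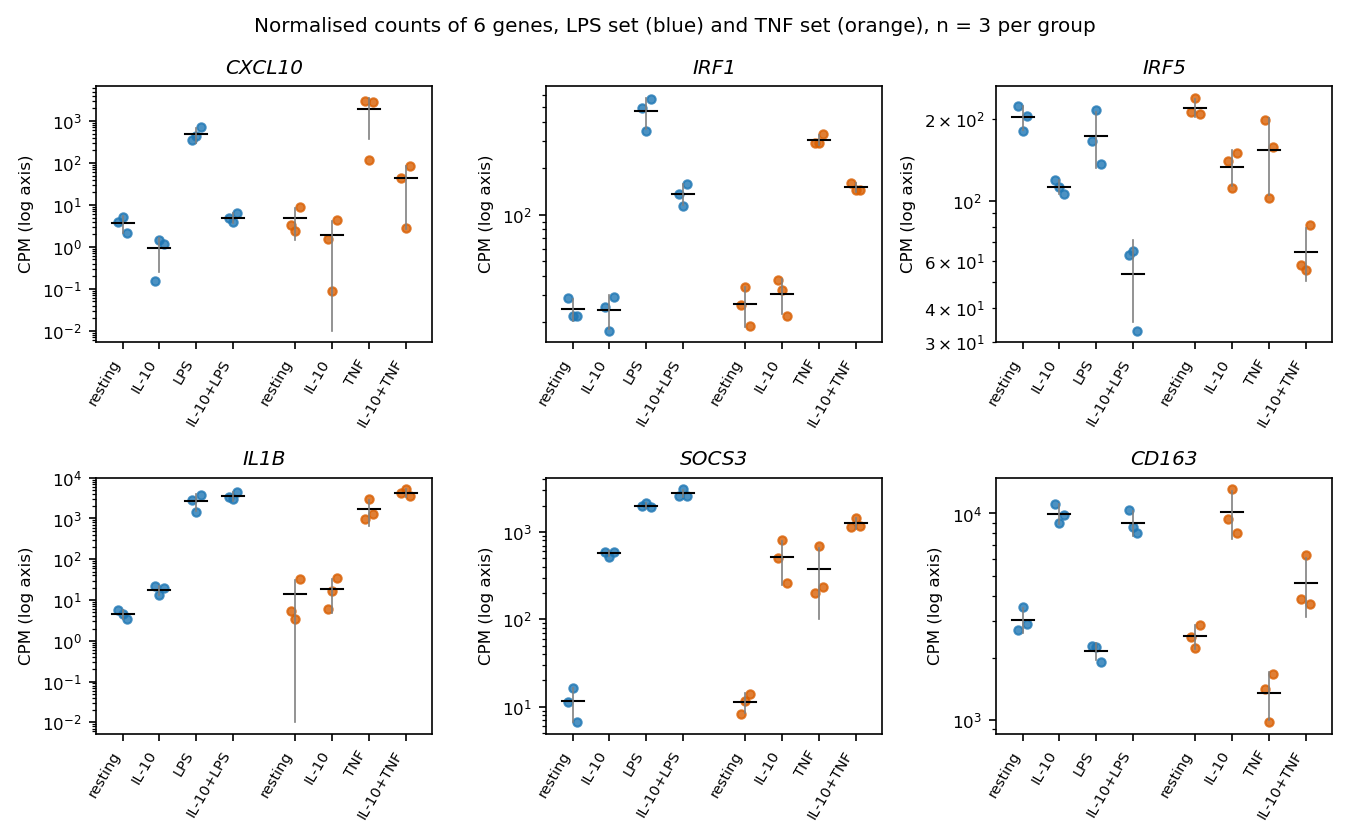
Level of CXCL10, IRF1, IRF5, IL1B, SOCS3 and CD163 in each library (points, CPM on a log axis; blue for the LPS set, orange for the TNF set), with the mean as a black bar and 1 SD as a grey line, n = 3 per group; a lower end below 0.01 CPM is drawn at 0.01. CXCL10 was at 490 CPM on average with LPS and 4.99 with IL-10 plus LPS, while IL1B was at 2710 and 3573.

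The IL-10 effect with LPS differed from that without LPS for 300 genes, 86 in the positive and 214 in the negative direction. TNIP3 (-6.79 ± 0.46), CD274 (-5.70 ± 0.53), IL2RA (-5.19 ± 1.01) and SOCS3 (-5.19 ± 0.36) rose with IL-10 in resting cells more than in LPS-treated cells. CXCL10 (-4.75 ± 0.81), SP110 (-3.40 ± 0.24), IRF7 (-2.58 ± 0.21) and IRF1 (-1.75 ± 0.31, adjusted p = 0.0078) went the other way round, with a larger decrease under LPS. TFAP4, a transcription factor gene, fell with IL-10 in resting cells (-1.92 ± 0.30) and rose with it under LPS (1.36 ± 0.30), a difference of 3.28 ± 0.42, and ZFP36L2 (3.08 ± 0.48) and FAM78A (2.49 ± 0.47) had the next largest positive differences among abundant genes. By list, 16 of 44 interferon-stimulated, 12 of 32 interferon-gamma-type and 7 of 28 STAT3 target genes had a negative difference (adjusted p = 1.2e-20, 1.8e-12 and 1.8e-07, and 0.093 for each with an estimated correlation). TNF (-1.31 ± 0.40, adjusted p = 0.11, and 0.015 with the replicate block) and IL1B (-1.60 ± 0.47, adjusted p = 0.10, and 0.025 with the block) were not called. Counts depended on the fit, at 696 with the replicate block, 593 by DESeq2, 179 after thinning and 185 without resting replicate 3.

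LPS induced 1641 genes at least 2-fold, and IL-10 lowered 262 of these (16.0%), 39 of them interferon-stimulated genes. With the replicate block the overlap was 395. Sets of these sizes would share 89.0 genes if independent. IL-10 raised 82 of the induced genes (88.3 expected). Of 1528 genes that LPS lowered at least 2-fold, IL-10 raised 195 (82.2 expected) and lowered 48 (82.9 expected). In simulations without an IL-10 effect, in which the LPS libraries are shared in the same way, 56.1% of induced genes had a negative IL-10 change, against 64.7% here. Part of the lean towards negative changes may thus come from the shared LPS libraries. The simulations called 0.1 genes lower on average and shared at most 1. No IL-10 effect was put in, so this shared count is no reference for the 262. How far shared libraries add to the overlap when IL-10 has an effect cannot be read from the simulations. Genes lowered by LPS were not counted in them. CRLF2, a cytokine receptor subunit, was among the 262, at 61.3 ± 13.8 CPM with LPS and 0.938 ± 0.340 with IL-10 plus LPS.

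TNF, a cytokine that signals through TNFR1 and TNFR2, changed 5552 of 10811 genes at 6 h, 2602 higher and 2950 lower. EBI3, a subunit of IL-27 and IL-35 (ENSG00000105246, chromosome 19, 4229498 to 4237531), rose from 0.167 ± 0.0643 to 296 ± 171 CPM (10.92 ± 0.68, adjusted p = 8.9e-07, n = 3 per group). TNFRSF4 (10.28 ± 0.61), the chemokine CCL8 (10.24 ± 1.38), TNFAIP6 (9.72 ± 0.53) and the metalloreductase STEAP4 (9.55 ± 0.76) came next among abundant genes. SELENOP (-5.67 ± 0.70), SLC7A8 (-5.42 ± 0.31), FAM13A (-5.40 ± 0.33), JAML (-5.07 ± 0.95) and ZNF395 (-4.94 ± 0.29) fell most among them. All 23 measured chemokines rose, as did 41 of 44 interferon-stimulated genes (RSAD2, 5.62 ± 1.58), 28 of 31 NF-kB genes and 15 of 17 inflammatory cytokines, where 1 fell. Camera gave adjusted p = 2.5e-08 for chemokines, 2.5e-08 for interferon-stimulated genes, 3.2e-17 for NF-kB genes and 1.6e-05 for cytokines, and 0.080, 0.57, 0.082 and 0.060 with an estimated correlation. IRF1 rose by 3.55 ± 0.24, and IRF5 was -0.53 ± 0.23 (adjusted p = 0.078, and 0.039 with a replicate block). Scavenger and phagocytic receptors had 14 lower and 2 higher of 26 (MERTK, -2.61 ± 0.54), and monocyte identity genes 10 lower and 4 higher of 20 (CCR2, -3.83 ± 0.70). CXCL10 varied widely between donors with TNF, at 1969 ± 1604 CPM. Called genes were 46.9% higher, but 25.5% by library size alone, with a median shift of -0.29. After thinning 3276 genes were called.

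IL-10 alone changed 1187 genes in the TNF set, 630 higher and 557 lower. ENPP2 (7.39 ± 0.88), CEMIP (7.12 ± 0.87) and the hyaluronan receptor LYVE1 (6.81 ± 0.85) rose most among abundant genes. FCN1 (-4.07 ± 0.25), PDGFB (-4.07 ± 0.77) and ADA2 (-3.55 ± 0.47) fell most among them. SOCS3 rose by 5.54 ± 0.59, PIM1 by 4.98 ± 0.38 and CR1 by 5.71 ± 0.57. Of 28 STAT3 targets 15 rose and 1 fell (adjusted p = 2.0e-11, and 0.11 with an estimated correlation). Of 44 interferon-stimulated genes 1 rose, LGALS9 (0.98 ± 0.20), and none fell, with a median of -0.97 (adjusted p = 0.089). With the replicate block 6 fell and 1 rose, with adjusted p = 0.0083, against 0.79 with an estimated correlation. IRF5 was -0.73 ± 0.23 (adjusted p = 0.071, and 0.035 with the block). IL-10 alone moved 389 genes up and 194 down in both sets, where 33.8 and 20.9 would be expected for independent sets, and 0 up in the LPS set and down in the TNF set. Fold changes correlated across genes (r = 0.790, n = 10558 genes), and the block gave 616 and 394 shared genes, with 2 up in the LPS set and down in the TNF set. Called genes numbered 1978 with the block, 2878 with a pair of donor numbers exchanged in it, 1808 by DESeq2, 535 in a fit of the 2 groups alone and 510 after thinning, and 561, 666 and 745 without resting replicate 1, resting replicate 2 and IL-10 replicate 2 (354 shared by both sets without resting replicate 1). By library size alone 33.6% of called genes were higher in place of 53.1%, at a median shift of -0.12.

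In TNF-treated cells, prior IL-10 raised FAM20A, a pseudokinase of the secretory pathway, 110-fold (6.77 ± 0.79), CR1 (5.92 ± 0.61), LYVE1 (5.91 ± 0.95), ENPP2 (4.66 ± 0.75) and KCNJ15 (4.55 ± 0.55), n = 3 per group. CXCL10 fell from 1969 ± 1604 to 43.8 ± 41.0 CPM (-5.50 ± 1.49, adjusted p = 0.045), with APOBEC3A (-5.16 ± 1.08), FCN1 (-4.39 ± 0.25), FGL2 (-3.81 ± 0.55) and JUP (-3.49 ± 0.74). IRF1 fell from 307 ± 24.6 to 150 ± 9.65 CPM (-1.03 ± 0.22, adjusted p = 0.016) and IRF5 from 154 ± 48.7 to 64.6 ± 14.3 CPM (-1.25 ± 0.24, adjusted p = 0.0098). TNF (-1.12 ± 0.45), IL6 (1.01 ± 0.72) and IL1B (1.31 ± 0.81) were not called, and SOCS3 was 1.74 ± 0.49 (adjusted p = 0.054, and 0.011 with the replicate block). In all, 923 genes were called, 534 higher and 389 lower.

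Interferon-stimulated genes fell in 16 of 44 cases with IL-10 under TNF, 43 when adjusted over the list alone and 41 with the replicate block, with a median of -2.36 (adjusted p = 2.0e-21, and 0.31 with an estimated correlation). Interferon-gamma-type genes had 15 lower and 2 higher of 32 (CXCL9, -4.94 ± 1.08; list adjusted p = 1.9e-07, and 0.31 with an estimated correlation). STAT3 targets had 11 higher and 1 lower of 28, with MARCO at 3.23 ± 0.39 and TNFRSF1B, which encodes TNFR2, at 2.90 ± 0.25 (adjusted p = 1.5e-08, and 0.31 with an estimated correlation). Monocyte identity genes had 10 higher and 1 lower of 20 (VCAN, 4.42 ± 0.81; adjusted p = 0.00037, and 0.32 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 23 cases, 7 when adjusted over the list alone, such as STARD4 (-1.75 ± 0.31), MVK (-0.99 ± 0.25) and FDFT1 (-0.98 ± 0.17), with adjusted p = 1.7e-06, and 0.31 with an estimated correlation. CD86 fell by 1.16 ± 0.32 (adjusted p = 0.046, 0.057 with the block, and 0.038 with a pair of donor numbers exchanged in the block). The total was 1451 with the block, 2161 with a pair of donor numbers exchanged in the block, 1449 by DESeq2 and 342 after thinning, and 500, 353, 421 and 361 without TNF replicate 1, TNF replicate 3, IL-10 plus TNF replicate 1 and IL-10 plus TNF replicate 2.

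Of 1272 genes that TNF induced at least 2-fold, IL-10 lowered 140, against 45.8 expected for independent sets. The replicate block gave 214 and DESeq2 225. IL-10 also raised 88 of the induced genes (62.8 expected, and 152 against 102 with the block). Of 1732 genes that TNF lowered at least 2-fold, IL-10 raised 156 (85.6 expected) and lowered 80 (62.3 expected). Among the 140 were 14 interferon-stimulated and 14 interferon-gamma-type genes, and among the 214 with the block 38 and 14. A negative IL-10 change was seen for 54.0% of induced genes, and for 56.3% in simulations without an IL-10 effect that share the TNF libraries. The share of induced genes moving down was thus no higher than without an effect. The simulations called 0 genes lower, since no IL-10 effect was put in, so their shared count is no reference for the 140. How far shared libraries add to the overlap when IL-10 has an effect cannot be read from the simulations. Genes lowered by TNF were not counted in them. Counts of lowered genes were 61, 39, 44 and 32 without TNF replicate 1, TNF replicate 3, IL-10 plus TNF replicate 1 and IL-10 plus TNF replicate 2, and 211 without TNF replicate 2.

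The IL-10 effect with TNF differed from that without TNF for 19 genes, 9 in the positive and 10 in the negative direction. PLD1, a phospholipase (2.97 ± 0.45), TNFRSF1B (2.24 ± 0.33) and MFHAS1 (2.19 ± 0.19) had the largest positive differences among abundant genes, and the chemokine CXCL6 (-4.42 ± 0.62), the kinase PIM1 (-3.65 ± 0.47) and LGALS9 (-1.84 ± 0.28) the largest negative ones. SOCS3 stood at -3.79 ± 0.71 (adjusted p = 0.067, and 0.026 with the replicate block). No cholesterol synthesis gene was called of 23, but 11 were lower when adjusted over the list alone, and the list median was -0.92 (adjusted p = 7.1e-13, and 0.22 with an estimated correlation). The count was 156 with the block, 747 with a pair of donor numbers exchanged in the block, 400 by DESeq2 and 10 after thinning, and by library size alone 76.9% of 26 called genes were positive in place of 47.4%, at a median shift of 0.10. The count was 1 without resting replicate 1, resting replicate 2, TNF replicate 3, IL-10 plus TNF replicate 1 or IL-10 plus TNF replicate 3, 2 without IL-10 replicate 1 or IL-10 plus TNF replicate 2, 4 without IL-10 replicate 2 or TNF replicate 1, 30 without IL-10 replicate 3, 149 without resting replicate 3 and 151 without TNF replicate 2.

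Tested directly in 1 fit, the IL-10 effect differed between LPS and TNF for 34 of 10558 genes, 16 more positive and 18 more negative under LPS. LPS was given for 3 h and TNF for 6 h, in separate sets whose donors carry other numbers. The stimulus, the time and the set with its donors therefore cannot be told apart in this contrast. IL-10 raised ACOD1 under TNF (3.71 ± 0.57) but left it at -0.05 ± 0.34 under LPS, a difference of -3.78 ± 0.72. SMOX, spermine oxidase, fell under LPS (-2.14 ± 0.55) and rose under TNF (0.89 ± 0.23), a difference of -3.05 ± 0.62, and the myelin protein gene PMP22 differed by -2.91 ± 0.62. TGFBR2, a TGF-beta receptor, rose under LPS (2.88 ± 0.22) and was 0.59 ± 0.25 under TNF, a difference of 2.28 ± 0.34, with GAPT (2.35 ± 0.41) and the transporter SLCO2B1 (2.12 ± 0.27) beside it. Differences for IRF1 (-0.77 ± 0.32), IRF5 (-0.45 ± 0.34) and CXCL10 (-1.20 ± 1.47) were not called (adjusted p = 0.42, 0.75 and 0.90). No interferon-stimulated gene of 44 was called by edgeR, and 1 was higher and 1 lower with the replicate block (list median -0.59, adjusted p = 0.43, 0.0076 with the block, and 0.97 with an estimated correlation). IL-10 lowered 172 genes under both stimuli (21.2 expected; 344 with the block and 342 by DESeq2) and raised 221 (29.5 expected; 392 with the block). Fold changes correlated across genes (r = 0.686). For the genes lowered under both, leaving out TNF replicate 1, TNF replicate 3, IL-10 plus TNF replicate 1 or IL-10 plus TNF replicate 2 gave 78, 54, 60 and 47. The 34 became 161 with the block, 310 with a pair of donor numbers exchanged in it and 155 by DESeq2, 16 and 59 without LPS replicate 1 and 2, 17 without IL-10 plus LPS replicate 3, 70 and 15 without TNF replicate 2 and 3, and 19 without any 1 of the IL-10 plus TNF replicates.

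**Figure D2:**
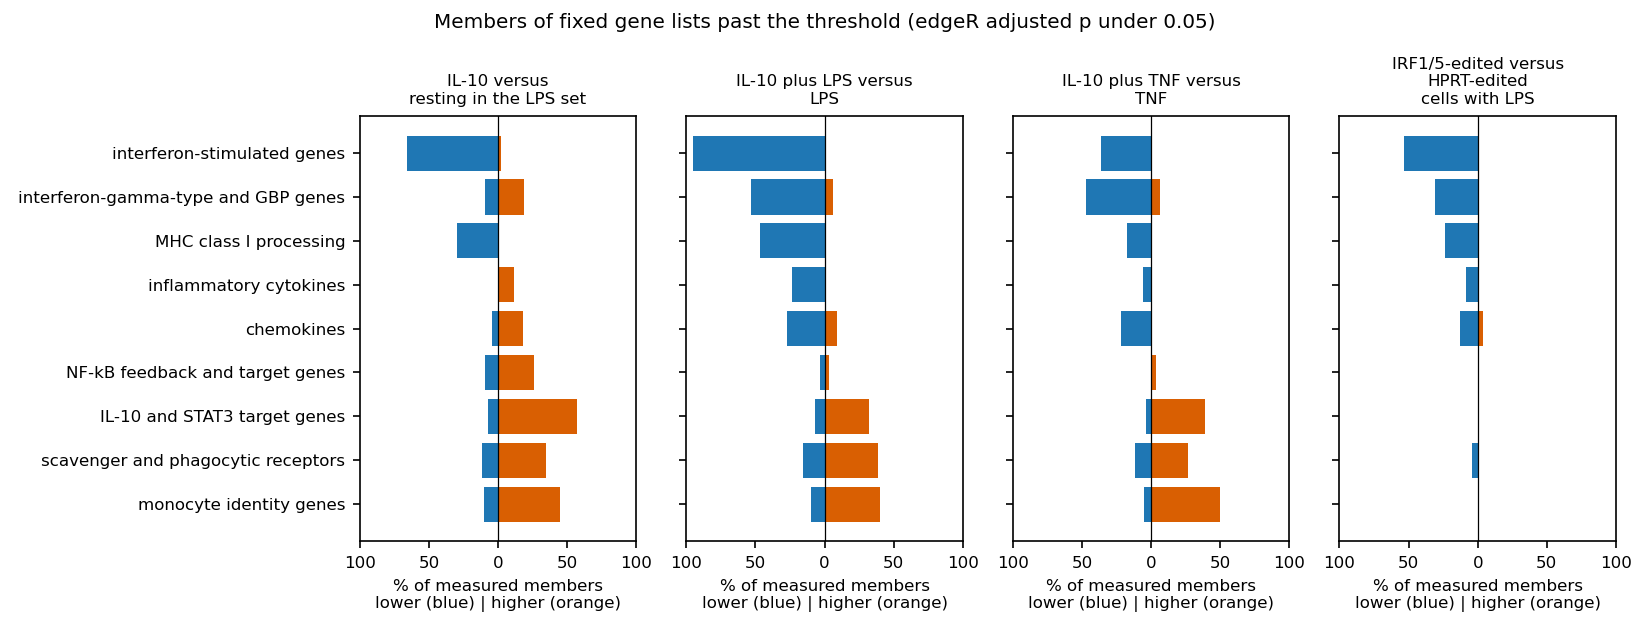
Share of the measured members of 9 gene lists called lower or higher in 4 comparisons, by edgeR at an adjusted p below 0.05 with n = 3 per group. Of 44 interferon-stimulated genes, 42 were called lower with IL-10 under LPS and 16 under TNF.

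After editing, IRF1 transcripts stood at 219, 102 and 181 CPM in the IRF1/5-edited libraries and at 314, 254 and 296 CPM in the HPRT-edited libraries (-0.80 ± 0.24, adjusted p = 0.22, and 5.5e-08 with the replicate block). IRF5 stood at 51.6, 56.5 and 55.5 CPM against 75.6, 103 and 74.2 CPM (-0.62 ± 0.19, adjusted p = 0.22, and 0.0044 with the block), so each edited library was below all 3 controls for both genes. HPRT1 (ENSG00000165704, chromosome X, 134460153 to 134520513) did not differ, at 37.9, 36.1 and 18.1 CPM in IRF1/5-edited cells and 37.4, 28.6 and 23.1 CPM in HPRT-edited cells (0.07 ± 0.29, adjusted p = 0.97). Transcript counts do not measure editing of the DNA, and no editing efficiency was used here.

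In LPS-treated cells, 85 genes were lower and 5 higher after IRF1/5 editing than after HPRT editing. CXCL10 fell from 240 ± 125 to 12.6 ± 7.59 CPM (-4.17 ± 0.52, adjusted p = 0.017, n = 3 per group), the chemokine CCL8 from 221 ± 131 to 12.7 ± 0.160 CPM (-4.11 ± 0.46), and RSAD2 (-4.01 ± 0.51), TNFSF10 (-3.96 ± 0.51) and the deubiquitinating enzyme USP18 (-3.20 ± 0.54) fell next. The chemokine CCL22 (ENSG00000102962, chromosome 16, 57358772 to 57366190) rose from 132 ± 30.7 to 412 ± 75.1 CPM (1.65 ± 0.20, adjusted p = 0.0023), with SYNPO (2.71 ± 0.45, from 3, 3 and 2 counts in the controls), CRLF2 (1.41 ± 0.28), NIFK (1.19 ± 0.24) and the hyaluronan synthase HAS1 (0.79 ± 0.16). IRF7 fell from 230 to 76.6 CPM (-1.55 ± 0.19). IL6 (-0.20 ± 0.33), IL1B (0.19 ± 0.27), SOCS3 (0.16 ± 0.18) and CD163 (-0.14 ± 0.29) were not called, nor were TNF (-0.74 ± 0.37, adjusted p = 0.59, and 8.5e-08 with the block) and IL12B (1.27 ± 0.51, adjusted p = 0.43, and 0.0099 with the block). IFNB1, the interferon-beta gene and the only interferon gene measured, had 5, 3 and 3 counts in HPRT-edited libraries and 0 in all IRF1/5-edited libraries (adjusted p = 0.16).

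Interferon-stimulated genes fell after editing in 24 of 45 cases, 42 when adjusted over the list alone with 1 rising, and 36 with the replicate block, with a median of -1.90 (adjusted p = 2.9e-64, and 0.090 with an estimated correlation). Interferon-gamma-type genes fell in 10 of 32 cases, 21 over the list alone and 19 with the block, such as BATF2 (-2.68 ± 0.39) and GBP3 (-2.38 ± 0.33; adjusted p = 3.0e-25, and 0.090 with an estimated correlation). MHC class I processing genes fell in 4 of 17 cases, 14 with the block, including PSMB9 (-1.90 ± 0.35), TAP1 (-1.75 ± 0.25) and their activator NLRC5 (-1.61 ± 0.32; adjusted p = 2.5e-15, and 0.16 with an estimated correlation). No NF-kB feedback and target gene of 31 was called by edgeR, with 3 higher and 3 lower under the block, a median of -0.01 and adjusted p = 0.99. Inflammatory cytokines fell in 2 of 23 cases (IL27, -2.11 ± 0.38; 6 lower and 1 higher with the block), and chemokines had 3 lower and 1 higher of 24 (8 and 3 with the block). Glycolysis genes had 0 called of 25 without the block, and 11 higher and 1 lower with it. Only 1 T and NK cell marker and 2 B and plasma cell markers were measured, and none of them, nor of 7 platelet, 7 neutrophil and 8 dendritic cell markers, was called. The total of 90 became 806 with the block (246 higher, 560 lower) and 145 by DESeq2, and 47, 47 and 31 without HPRT-edited replicate 2, HPRT-edited replicate 3 and IRF1/5-edited replicate 1.

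Genes lowered by IL-10 under LPS and genes lower after editing were then compared over the 10930 genes in both tables. Of 84 genes lower after editing 68 (81.0%) were among the 600 lower with IL-10, where 4.61 would be expected for independent sets. No library is shared, though the donor numbers are the same. With the replicate block the overlap was 249 (47.1 expected). CXCL10, RSAD2, TNFSF10, USP18 and CCL8 were in both sets. Without the block, CRLF2 alone was lower with IL-10 (-5.93 ± 0.53) and higher after editing. With it, 31 genes were (21.8 expected), and 29 were higher with IL-10 and lower after editing. There were 0 genes higher in both by edgeR (0.210 expected; 50 with the block). Of 262 genes induced by LPS and called lower with IL-10, 56 were lower after editing (21.4%, with a median change of -0.56). Of 1365 induced genes not called lower with IL-10, 8 were (0.586%, median 0.01). With the block in the editing fit alone, and the IL-10 sets unchanged, 121 (46.2%) and 120 (8.79%) were lower after editing. Genes not called lower can still be lowered within donors. The overlap was 40, 39, 26 and 39 without HPRT-edited replicate 2, HPRT-edited replicate 3, IRF1/5-edited replicate 1 and IRF1/5-edited replicate 3.

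**Figure D3:**
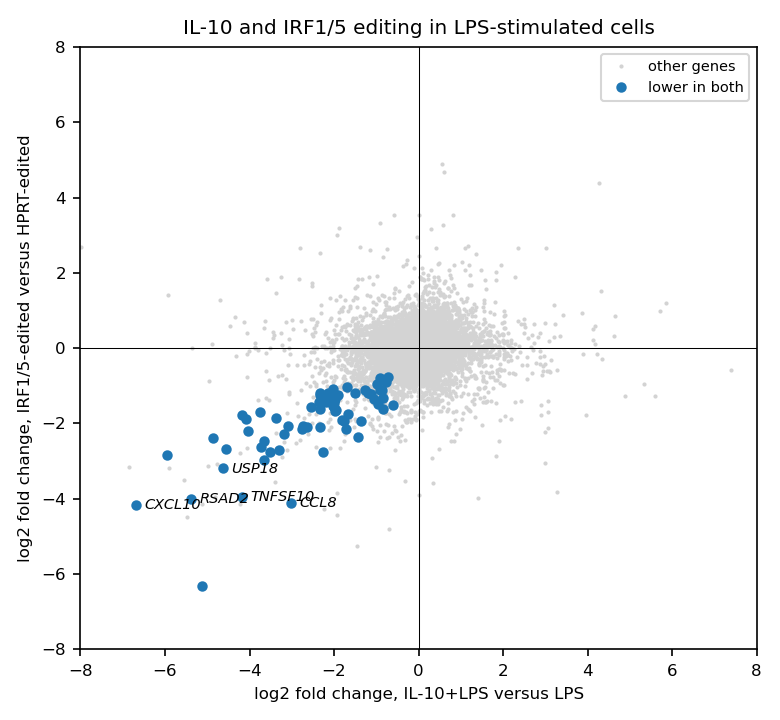
Log2 fold change with IL-10 under LPS (x axis) and after IRF1/5 editing (y axis) for 10918 genes, with the 68 genes called lower in both in blue and 1 gene outside the axes not drawn (n = 3 per group). CXCL10 was at -6.69 and -4.17.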

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

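The results in the next paragraph stand here because a test of the difference itself found IL-10 effects that differ between settings. In this part the tests of donor numbers, of the direction after editing, and of donor spread and effect size under TNF were chosen only after the results were seen.

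The IL-10 effect differed with and without LPS for 300 genes: TFAP4 (3.28), ZFP36L2 (3.08), FAM78A (2.49), TNIP3 (-6.79), CD274 (-5.70), IL2RA (-5.19), CXCL10 (-4.75), IRF1 (-1.75) and SOCS3 (-5.19). It differed with and without TNF for 19 genes: PLD1 (2.97), TNFRSF1B (2.24), MFHAS1 (2.19), CXCL6 (-4.42), PIM1 (-3.65) and LGALS9 (-1.84). Between LPS and TNF it differed for 34 genes: GAPT (2.35), TGFBR2 (2.28), SLCO2B1 (2.12), ACOD1 (-3.78), SMOX (-3.05) and PMP22 (-2.91). Among 50 splits of the libraries, the real one alone (1 of 50) gave as many as the 300 genes for LPS. The highest other gave 194, in a split that fully reversed the IL-10 groups of the cells without LPS. Splits that mix libraries with and without IL-10 add the IL-10 effect to the spread, which lowers their counts. The 1 of 50 therefore does not exclude a chance assignment for LPS either. For TNF 4 of 50 gave at least 19, the highest 84, and between LPS and TNF 6 of 40 gave at least 34, the highest 1293. Apart from the real split these were 3 and 5 splits. All of them kept or fully reversed the real IL-10 groups on at least 1 side of the difference. Such splits still carry an IL-10 effect, so they cannot decide whether a chance assignment of libraries gives as many genes for these 2 results. For the other 7 comparisons only 10 splits exist, so a share under 0.05 cannot be reached; the real split was the only 1 of 10 with as many called genes, the highest other gave 1 with IL-10 under LPS and 0 elsewhere, and 4 of the 10 part as many donor pairs.

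In the TNF group, 2 of 3 libraries varied together with libraries of another donor number. Over 300 donor-varying genes among 3766 that TNF does not move on average, 1 TNF library matched its own number best and 2 matched another. All 3 IL-10 plus TNF libraries matched their own. The correlation with the best number was at least 0.546, and that of the exchanged libraries with their own number at most -0.205. An exchange of 2 numbers within the group fits. Donor differences in the TNF response alone are less likely, since these genes were not called with TNF and had a small average change. Opposite responses of single donors would pass that rule, so they were not excluded. Which step would have exchanged the numbers stays open. The unblocked tests do not use the numbers, but the rule of the same direction in all 3 donors, used to name genes, does. With the deposited numbers it held for 5502 of 5552 genes called with TNF and 921 of 923 called for IL-10 under TNF. The rule was not applied with exchanged numbers.

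Of 90 genes called after IRF1/5 editing, 85 were lower. The edited groups had 3311945 and 3310665 counts in total, a log2 ratio of 0.00056, and the 10 most abundant genes could shift the others by at most 0.0325, against a smallest called decrease of 0.77, which argues against depth and abundant genes. An equal loss across LPS-induced genes is argued against by all 1627 of these, with a median of -0.0358 and the lowest decile below -1.15, against a median of -1.65 for the 85. With the replicate block 560 of 806 were lower, and a weaker response of part of the LPS program stays open. IRF1 transcripts were at -0.80, but with 1 set of guides per arm, an effect of the editing itself and of these guides cannot be told apart.

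Under TNF, 16 of 44 interferon-stimulated genes were lower with IL-10, against 42 under LPS. Total counts were 45285323 with TNF and 59518244 with LPS, but 71840197 with IL-10 plus TNF and 47593542 with IL-10 plus LPS. The TNF side was thus not the shallower one in both groups. Depth does not account for the lower number, as 40 were still lower under LPS after thinning to 746227 counts per library. Spread between donors fits: the median SD of the list was 1.32 log2 units with TNF, 1.57 with IL-10 plus TNF and 0.24 with LPS. A block gave 41 with the exchanged numbers and also with the deposited ones, so the exchange made no difference to this count. Leaving out 1 library gave 2, 29 and 0 (TNF replicates 1, 2 and 3) or 1, 2 and 18 (IL-10 plus TNF replicates 1, 2 and 3). Whether the effect is also smaller under TNF stays open, with 38 of 44 genes lowered less but 2 differing in a joint fit blocked by the deposited numbers, and 2 with the exchanged ones.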

How the results depend on the processing

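No called gene changed direction under the replicate block, and RLE size factors and filterByExpr moved no total by more than 1.5 times. Leaving out single libraries kept the totals for LPS (4285 to 4998), TNF (4430 to 5820), IL-10 under LPS (814 to 1206), IL-10 alone in the LPS set (672 to 1023) and LPS-induced genes lowered by IL-10 (175 to 281) within that range. Thinning, the exchanged numbers, equal depth, and leaving out libraries for the overlaps and the difference between stimuli were chosen after the data were seen. Apart from the calls given beside their results, the block changed no call of a named gene; list tests passed only with it for chemokines (0.15 to 0.045) and dendritic cell markers (0.15 to 0.025) with IL-10 alone in the LPS set and for metallothioneins (0.14 to 0.011) and monocyte identity genes (0.20 to 0.039) after editing, and only without it for AP-1, EGR and MAF factors between the stimuli (0.037 to 0.061). None of these passed with an estimated correlation. Calls of named genes were lost in 423 values with 1 library left out (2618 kept their side of the threshold, 13 gained a call), 63 after thinning, 33 in fits of the 2 groups alone, 12 by library size alone, 6 at equal depth, 4 with filterByExpr, 3 by DESeq2 and 3 with RLE factors. Thinning lowers counts by construction; for all other changes the cause was not tested, including the rises when 1 library was left out. Depth was lowest in the edited cells, with 746227 counts in the shallowest library.

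Replicate block: IL-10 under LPS 2032, alone in the LPS set 1755, by LPS 696; IL-10 under TNF 1451, alone in the TNF set 1978, by TNF 156. Editing gave 806 and the difference between LPS and TNF 161. Of LPS-induced genes 395 were lowered, of TNF-induced genes 214; 249 were lower with IL-10 and after editing, 344 under both stimuli, and 1010 changed with IL-10 alone in both sets. With exchanged numbers the totals were 2161 under TNF, 2878 alone in the TNF set, 747 by TNF and 310 between LPS and TNF. Named genes called only with it, or with the block as deposited, were IRF1 by TNF (adjusted p = 0.020) and IL6 between LPS and TNF (0.016), and IRF5 (0.018 with TNF, 0.014 with IL-10 alone) and SOCS3 (0.0065 under TNF, 0.011 by TNF).

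DESeq2 called 593 by LPS, 1449 under TNF, 1808 alone in the TNF set, 400 by TNF, 145 after editing, 155 between stimuli, 225 TNF-induced genes lowered and 342 lowered under both stimuli. A fit of the 2 groups alone called 535 for IL-10 in the TNF set. Thinned, the totals were 750 under LPS, 179 by LPS, 3276 for TNF, 342 under TNF, 510 alone in the TNF set and 10 by TNF.

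Leaving out 1 library gave 185 to 387 by LPS, 353 to 1044 under TNF, 561 to 1655 alone in the TNF set, 1 to 151 by TNF, 31 to 118 after editing and 15 to 70 between stimuli. It gave 32 to 211 TNF-induced genes lowered, 26 to 90 lower with IL-10 and after editing, 47 to 247 under both stimuli and 354 to 600 with IL-10 alone in both sets. Of 99 list tests that passed, 10 did so with an estimated correlation. RPL30 in LPS versus resting reversed, from 0.38 to -0.0712 by library size alone, a scaling that shifted the median of all genes by -0.45.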

Other observations

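The hyaluronan synthase HAS1 rose with LPS (10.68 ± 1.25) and was -0.47 ± 0.99 with TNF (adjusted p = 0.71). VCAN, which encodes a hyaluronan-binding proteoglycan, fell with LPS (-1.71 ± 0.23) and with TNF (-1.92 ± 0.73), and CEMIP rose with both (3.95 ± 0.73 and 3.01 ± 0.74). CCL22, higher after editing, fell with IL-10 under TNF (-2.60 ± 0.66).

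In this part the tests of resting levels and of cholesterol synthesis genes were planned before their results were seen; the direct comparison of the sets and the test of the overlap in the form given here were chosen only afterwards. IL-10 alone lowered 29 interferon-stimulated genes in the LPS set and 0 in the TNF set (6 with the replicate block). To test if higher resting levels in the LPS set go with this, mean log2 CPM of the list was compared. It was 4.93 ± 0.24 in the LPS set and 4.68 ± 0.42 in the TNF set, a difference of 0.24. This is under the difference that the rule written beforehand asked for. With the spread between libraries added to that rule, it was not clearly under it, so the question stays open. A direct comparison of IL-10 alone between the sets, added afterwards, called 0 genes by edgeR (207 at an unadjusted p below 0.05) and 5 with the replicate block, and 0 of the list in either fit, so a difference between the sets is not shown.

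To test if the overlap of IL-10 and editing rests on the interferon lists, these were left out. The median change after editing was -0.33 for 211 LPS-induced genes called lower with IL-10 and 0.01 for 1354 not called lower, a difference of -0.34. It lay between -0.47 and -0.24 in the 3 donors, and between -0.36 and -0.28 with each of 6 edited libraries left out. Of the 211 genes, 29 were lower after editing, and 80 with the block in the editing fit, so the overlap is not confined to those lists. The lists do not hold every gene that responds to interferon. The test therefore cannot tell whether the overlap extends beyond interferon responses.

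To test if 1 library explains the negative IL-10 by TNF difference of cholesterol synthesis genes, each of 12 libraries was left out in turn. The list median stayed between -1.08 and -0.68, which argues against 1 library as the source.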
